A study of Danio rerio with 2 samples.

How the data were processed

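The measurement was single-cell RNA sequencing (10x Genomics Chromium, v2 chemistry) of zebrafish (Danio rerio) cells sorted by flow cytometry for a transgenic ZsYellow reporter of nkx2.5, a cardiac homeobox gene. Embryos of the AB/TU background were dissociated at 28 hours after fertilization, per the labels. There were 2 libraries, 1 from control embryos and 1 from Pbx4-depleted embryos. The labels do not say how Pbx4 was depleted. Pbx4 is a homeodomain transcription factor of the TALE class and a partner of Meis and Hox proteins. Per the submitters' processing notes, reads were processed with Cell Ranger against the zebrafish build GRCz10 (danRer10). The Cell Ranger version, its settings and the annotation release are not given in the sources used here.

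The deposited values are whole-number UMI counts (unique molecular identifiers, 1 per captured transcript molecule) per gene and barcode, per the file headers, with no normalization. Each library listed 35117 genes and all 737280 barcodes, so cells still had to be called. Gene symbols were taken from the deposited gene list. A second table of current names gave a symbol for 27000 of the 35117 gene identifiers and was used where a listed symbol was absent from the files. In the files, 501 symbols were shared by several identifiers, and genes of one symbol were kept apart by identifier. The sequence of the ZsYellow transgene is not among the listed genes, and neither are ltbp3 and hoxa3a.

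A barcode was called a cell when its UMI total reached 10% of the 99th percentile of the 4000 barcodes with most UMIs in its library, with at least 500 UMIs, at least 200 detected genes and at most 20% mitochondrial UMIs. About 4000 cells entered each library preparation, per the labels. The rule gave a minimum of 3533 UMIs in the control and 2846 in the Pbx4-depleted library. Doublets were scored in each library with scrublet as included in scanpy 1.11.5, at an expected rate of 3%. It marked 1 control barcode (0.0340%) and 3 Pbx4-depleted barcodes (0.123%), which were left out. So few marks mean that the caller in effect did not work, and doublets remain among the cells.

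Cells of both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were scaled with values limited at 10, and 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 were used (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). This gave 25 clusters. Names came from 17 marker lists written before the data were examined, of whose 254 symbols 243 were found. A marker counted for a cluster when it was detected in at least 10% of its cells and at least 2-fold higher than in the other cells, limits that were not part of the rules set in advance. At least 3 markers were needed, and a cluster whose 10 leading genes held more markers of another class than of its own stayed unnamed. A cluster with neural crest markers also stayed unnamed when posterior Hox genes were among its 10 leading genes, as in cluster 16, which had 4 such markers. There were 18 named clusters: 4 of cardiomyocytes, 4 of pharyngeal mesoderm, 3 of endothelium or endocardium, 3 neural, 2 of skeletal muscle and 2 of epidermis. The other 7 were unnamed, among them cluster 0, led by rdh10a, ackr3b, aldh1a2 and isl2a, which was compared by its number because it was the largest cluster, a choice made after the clusters were seen. Unnamed clusters 6, 10 and 13 also held more than 50 cells of each library and were not compared. The neural class is mixed: cluster 12 is led by pigment cell genes such as gch2 and cluster 21 by lens crystallin genes such as crybb1. Each of these names is a likeness to marker genes, not a lineage trace.

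UMIs were summed over the cells of a class in each library and expressed as CPM, the counts scaled to the same UMI total in every class and library. With 1 library per group there is no replicate check, no test and no p-value, and cells were not used as replicates. CPM values carry exact Poisson 95% intervals, ratios of the Pbx4-depleted to the control value carry conditional binomial 95% intervals, and shares of cells carry exact Clopper-Pearson 95% intervals. For ratios of shares the conditional binomial interval treats numbers of cells as counts and is too wide, most of all for high shares. These intervals cover counting error only, not the variation between embryos, sorts or library preparations. Those of CPM and of CPM ratios take every UMI as independent, so they also leave out variation between the cells of a class. They are too narrow where few cells hold most of the UMIs. The median log2 ratio was also taken over all genes with at least 20 UMIs in each library. This cut favours genes that are higher in the library with fewer UMIs. The median was 0.07 in all cells, 0.18 in cardiomyocytes, 0.03 in pharyngeal mesoderm, 0.08 in endothelium or endocardium and 0.00 in cluster 0. List medians in cardiomyocytes are therefore given relative to 0.18.

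Genes were named by a rule set before the data were examined. Among genes with at least 30 UMIs and a CPM of at least 50 in the higher library, whose ratio interval left out 1, the 12 with the largest and the 12 with the smallest log2 ratio after adding 20 CPM to both values were taken, in cardiomyocytes, in pharyngeal mesoderm and in all cells. Clone-like symbols and mitochondrially encoded genes were passed over, and members of the fixed lists could be named as examples. There were 24 program lists, 3 of them by symbol pattern and the others with 386 symbols, of which 369 were found: cardiac sarcomere and contraction, ventricular chamber, atrial chamber, cardiac transcription factors, second heart field and arterial pole, pharyngeal mesoderm and head muscle, endothelial specification, smooth muscle and extracellular matrix, anterior Hox, TALE homeobox, retinoic acid pathway, FGF targets, BMP and TGF-beta targets, Wnt targets, Notch pathway, S phase, G2/M phase, damage response genes and cell cycle inhibitors, interferon response, dissociation and heat stress, glycolysis, nuclear oxidative phosphorylation, cytosolic ribosomal proteins and mitochondrially encoded genes. Some members of these lists are not reported here by name. Over the members with at least 20 UMIs, the median log2 ratio (1 CPM added) was given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, and with the numbers of members at least 1.5-fold higher, at least 1.5-fold lower and between. A percentile describes these 2 libraries.

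Shares of cells with UMIs of a gene or list were computed after thinning each cell to 5000 UMIs, a depth that kept 89.4% of the control and 87.6% of the Pbx4-depleted cells. This left out 312 and 304 shallower cells. Free RNA was read from barcodes with 10 to 100 UMIs. Ranked by UMIs, barcodes down to rank 67910 held at least 104 UMIs in the control and 136 in the Pbx4-depleted library. Barcodes between this range and the cell minimum, which can also hold free RNA, were thus left out. The range took 26872 control barcodes with 1295191 UMIs and 12530 Pbx4-depleted barcodes with 320049 UMIs. Free RNA ratios can therefore reflect which barcodes the range took in each library.

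The summing and list steps were tested on counts simulated from the means of the real genes. Both simulated libraries held counting error alone, without variation between cells, embryos, sorts or library preparations. The values below therefore check the computation, not the accuracy of a comparison of 1 library with 1 library. For the cardiomyocyte comparison (9240 genes, 200 of them changed), the ratio interval left out 1 for 97.0% of the genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, and for 4.31% of unchanged genes. For the pharyngeal mesoderm comparison (11058 genes, 200 changed) these values were 97.0%, 100%, 100% and 4.20%. In both, 24 of 24 genes named by the rule had truly been changed in that direction, 3 of 100 unchanged lists fell outside percentiles 2.5 to 97.5, and 20 of 20 lists shifted 1.3-fold lay above 97.5.

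The alternatives were other cell minimums (1000 UMIs, 2 times the minimum, the 4000 barcodes with most UMIs), no mitochondrial maximum, doublets kept, other clusterings (resolution 0.5 and 2.0, or without cell cycle genes), cell classes from marker scores without clusters, median-of-ratios scaling, the mean of per-cell CPM, free RNA subtraction of 5%, other low-count settings, and other depths and thresholds for the shares. Leaving out the 3% of cells with the highest doublet scores, cardiomyocyte cluster 17 or pharyngeal cluster 11 was chosen after seeing the data. All computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.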

Results

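The study asked how the loss of Pbx4 affects cardiac progenitors and differentiated cardiomyocytes, with attention to heart size, progenitor fates in the second heart field and proliferation. Cells carrying a ZsYellow reporter of nkx2.5 were sorted from zebrafish embryos at 28 hours after fertilization and profiled as 2 single-cell RNA libraries, 1 control and 1 Pbx4-depleted. The control library held 50506758 UMIs, of which 69.6% lay in 2941 called cells, with a median of 10510 UMIs and 2029 genes per cell. The Pbx4-depleted library held 45844020 UMIs, of which 62.2% lay in 2444 called cells, with a median of 10690 UMIs and 2151 genes. Median mitochondrial shares were 1.52% and 1.54%. Every comparison sets 1 library against 1 library, so none has a replicate check, and all intervals cover counting error only.

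The transcript of the targeted gene pbx4 was not lower in the Pbx4-depleted library. Over all called cells pbx4 measured 111 CPM (95% interval 107 to 114) in the control and 117 CPM (113 to 121) in the Pbx4-depleted library, a ratio of 1.06 (1.01 to 1.11). In cardiomyocytes it was 67.3 CPM in the control and 91.9 CPM in the Pbx4-depleted library, a ratio of 1.37 (1.21 to 1.54), and in pharyngeal mesoderm 122 and 131 CPM, a ratio of 1.08 (0.995 to 1.17). In endothelium or endocardium the ratio was 0.955 (0.788 to 1.16), in neural cells 0.899 (0.737 to 1.09) and in cluster 0 0.876 (0.789 to 0.971), where pbx4 was highest (191 and 167 CPM). A depletion that blocks translation or splicing need not lower counts at the transcript's 3' end, so these values do not check the labels.

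Cardiomyocytes made up a smaller share of the sorted cells in the Pbx4-depleted library, and pharyngeal mesoderm a larger one. Cells of the cardiomyocyte class, named from sarcomere genes such as myl7, tnnt2a and vmhc, were 773 of 2941 control cells (26.3%, 24.7 to 27.9) and 457 of 2444 Pbx4-depleted cells (18.7%, 17.2 to 20.3), a ratio of 0.711 (0.632 to 0.7997). Cells of the pharyngeal mesoderm class were 25.03% (23.5 to 26.6) and 36.5% (34.6 to 38.4), a ratio of 1.46 (1.32 to 1.61). This class joined unlike clusters. Clusters 1 and 5 were named from tbx1, tcf21 and ebf3a, none of which met the marker limits in clusters 3 and 11. Cluster 3 was named from nkx2.5, hand2, fgf8a and others, and cluster 11 from hand2, fgf10a and others. Endothelium or endocardium, named from kdrl, cdh5, tie1 and related genes, was 9.39% and 9.12%, a ratio of 0.972 (0.811 to 1.16). Over these 3 classes alone, cardiomyocytes were 43.3% and 29.1%, pharyngeal mesoderm 41.2% and 56.7%, and endothelium or endocardium 15.5% and 14.2%.

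Other cell types in the sort were neural cells (6.66% in the control and 4.34% in the Pbx4-depleted library), epidermis (1.90% and 0.818%) and skeletal muscle (1.02% and 1.15%). The 7 unnamed clusters together held 29.7% and 29.4%. The flow sort for ZsYellow and the UMI minimum for calling a cell (3533 and 2846 UMIs) can set all of these shares. Classing each cell by its marker scores in place of clusters called far fewer cells pharyngeal mesoderm, 7.55% and 9.94%, at a ratio of 1.32. The class held 13.2% and 19.4% of cells when they were clustered without cell cycle genes and 16.9% and 24.1% at resolution 2.0.

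**Figure D1:**
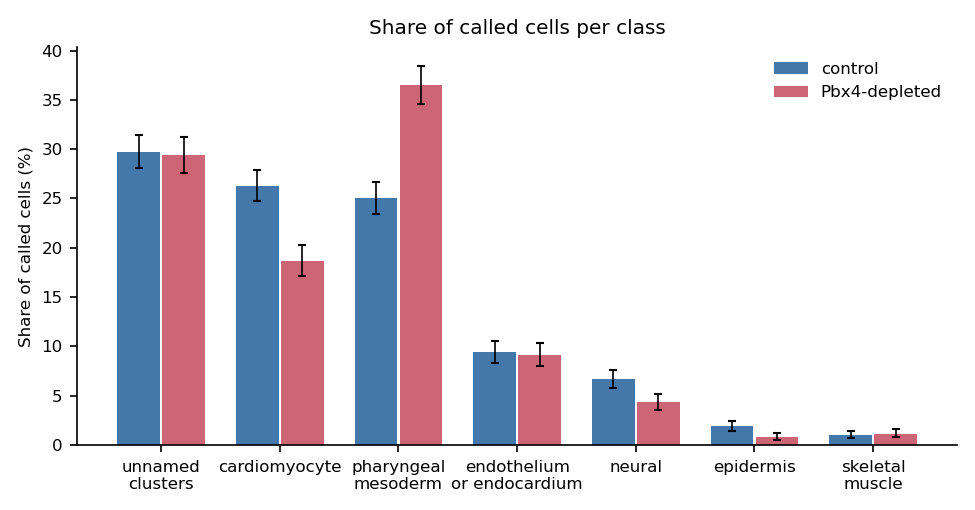
Share of called cells (percent, vertical axis) in each named class and in the unnamed clusters, for the control and the Pbx4-depleted library, with exact Clopper-Pearson 95% intervals as error bars. Cardiomyocytes were 26.3% of control and 18.7% of Pbx4-depleted cells, and pharyngeal mesoderm 25.03% and 36.5%.

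Within cardiomyocytes, Pbx4-depleted cells carried less RNA of hapln1a, lft2 and several muscle and glycolytic genes, and more RNA of hand2, the LIM-domain genes crip2 and fhl1a, and the glycogen phosphorylase gene pygl. The genes named as lower included hapln1a, which encodes a hyaluronan and proteoglycan link protein, at 1694 CPM in the control and 294 CPM in the Pbx4-depleted library (5.76-fold lower, 5.47 to 6.08), and lft2, which encodes the Nodal antagonist Lefty2, at 1354 and 250.2 CPM (5.41-fold lower, 5.11 to 5.73). Among the genes named as higher, pygl had the largest ratio, at 2.22 and 64.6 CPM (29.0, 18.3 to 48.8). The 2 libraries' cardiomyocytes lay mostly in different clusters, the control cells in clusters 4 and 2 and the Pbx4-depleted cells in clusters 2 and 8, and hapln1a and lft2 are among the leading genes of cluster 4 and fhl1a and cacna2d2a among those of cluster 8. Within cluster 2, which holds many cells of both, hapln1a was 534 and 68.4 CPM, lft2 1075 and 179.9 CPM, and pygl 1.68 and 50.1 CPM. At resolution 2.0 most cells of cluster 2 parted by library, into a cluster led by lft2 (224 control and 6 Pbx4-depleted cells in all) and one led by fhl1a (13 and 197).

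Among the other genes lower in Pbx4-depleted cardiomyocytes were several of the contractile apparatus. The myosin light chain gene myl10 measured 770.5 and 164 CPM (4.71-fold lower, 4.39 to 5.06) and the tropomyosin gene tpma 110.2 and 26.7 CPM (4.12-fold lower). The muscle actin gene actc1b was 139 and 43.5 CPM (3.19-fold lower). The chaperone gene hsp90aa1.1, whose product folds muscle myosin, was 88.6 and 17.9 CPM (4.96-fold lower, 4.00 to 6.20). The signalling peptide gene apln (apelin) was 169.5 and 44.2 CPM (3.83-fold lower, 3.34 to 4.42), and bokb, of the Bcl-2 family, 85.0 and 14.7 CPM (5.79-fold lower, 4.58 to 7.41). Genes of metabolism were also in this group: ldha (lactate dehydrogenase) was 108 and 28.8 CPM (3.76-fold lower), the fatty acid elongase gene elovl6 90.9 and 24.7 CPM (3.68-fold lower), and dhdhl 90.7 and 20.3 CPM (4.46-fold lower). The gene itm2cb was 104.8 and 27.7 CPM (3.79-fold lower). Of these, myl10, tpma and actc1b are also leading genes of the skeletal muscle clusters, and the skeletal muscle markers as a list had a relative median of -1.18 in cardiomyocytes (percentile 0), with 6 of 8 measured members lower, so a different amount of skeletal muscle RNA among these cells stays open, although tnni2b.1, another leading gene of those clusters, was higher.

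Among the genes higher in Pbx4-depleted cardiomyocytes, hand2, a transcription factor gene required for heart formation, measured 75.3 and 222 CPM (ratio 2.95, 2.68 to 3.25). The LIM-domain genes crip2 and fhl1a were 212 and 792 CPM (3.74, 3.54 to 3.95) and 246 and 699 CPM (2.84, 2.69 to 2.999). The gene of the Nodal coreceptor, tdgf1, was 149.9 and 393 CPM (2.62, 2.44 to 2.81), the calcium channel subunit gene cacna2d2a 43.7 and 123 CPM (2.82), and tnni2b.1, a troponin I gene, 25.8 and 88.3 CPM (3.43). The glycoprotein hormone gene stc2a was 67.7 and 195 CPM (2.89), gsg1l2a 64.0 and 169 CPM (2.64), and cdc42se1 29.3 and 90.2 CPM (3.08). The splicing factor gene snrpd1, at 271 and 690 CPM (ratio 2.55), and the chromatin remodelling gene smarcd1, at 44.6 and 133 CPM (ratio 2.98), were also higher in the neural class, by ratios of 1.705 and 1.74. So were, from few UMIs there, stc2a (8.71, 5.25 to 15.2), cacna2d2a (9.74), fhl1a (8.44), tnni2b.1 (7.97) and crip2 (2.41). In free RNA stc2a had a ratio of 3.12. Higher values were thus not limited to cells classed as cardiomyocytes. For fhl1a, cacna2d2a and tnni2b.1, leading genes of cardiac or skeletal muscle clusters, RNA carried over from those cells or doublets stay open as the source in neural cells. The neural ratio of hand2 was 1.33 (0.806 to 2.16).

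**Figure D2:**
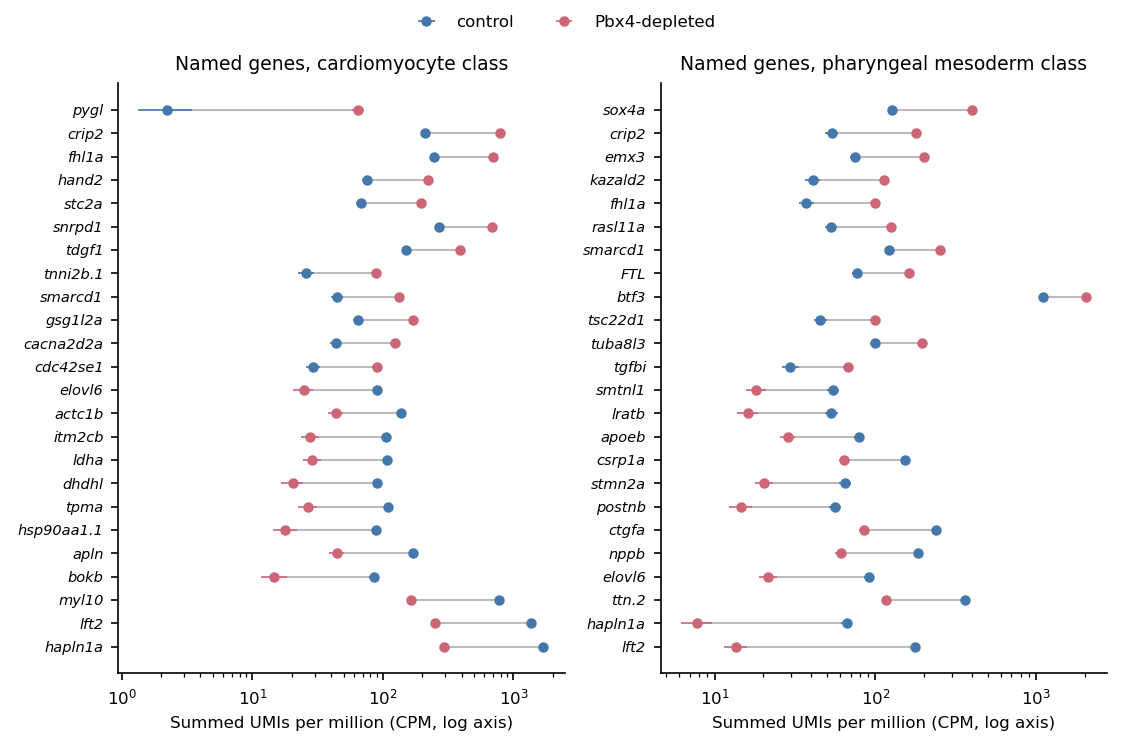
Summed UMIs of the genes named by the fixed rule, in CPM on a log axis, in the cardiomyocyte class (left) and the pharyngeal mesoderm class (right), with 1 point per library and exact Poisson 95% intervals. In both classes lft2 and hapln1a were over 5-fold lower in the Pbx4-depleted library, and crip2, fhl1a and smarcd1 were higher in it.

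In cardiomyocytes the median log2 ratio of all genes with at least 20 UMIs in each library was 0.18. List medians in this class are given relative to it. Random lists are not centred on this value, so a relative median below 0 can lie above matched genes, and the percentile gives that comparison. The sarcomere list lay below other genes, at -0.35 (percentile 0 of random lists), with 6 of 22 measured members at least 1.5-fold lower, 2 at least 1.5-fold higher and 14 between. The lower members were ttn.2 (titin, 1203 and 667 CPM), the calcium pump gene atp2a2a (589 and 233 CPM), mybpc3 (239.5 and 114 CPM), casq2, unc45b and the atrial myosin gene myh6 (118 and 67.8 CPM). Of these, atp2a2a, mybpc3 and myh6 met the marker limits in clusters 4 and 8 but not in cluster 2. That cluster held 271 of 773 control and 232 of 457 Pbx4-depleted cardiomyocytes, so another mixture of clusters stays open for these 3 genes. The higher ones were actn2b (77.0 and 119.5 CPM) and myh7ba. The most abundant members differed less: cmlc1 had a ratio of 1.02 (1.01 to 1.03), myl7 0.931 (0.924 to 0.939), and vmhc, the ventricular myosin gene, 0.773 (0.762 to 0.784) at 6628 and 5124 CPM.

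Chamber genes did not move together, and their levels can also differ through the mixture of cardiomyocyte clusters. The atrial list had a relative median of -0.96 (percentile 0.0900). Its 3 lower members of 5 were myh6, meis2b (30.6 and 16.0 CPM) and nr2f1a (15.0 and 5.27 CPM), and 2 were higher, among them tbx5a (15.7 and 24.5 CPM). The ventricular list had a relative median of 0.49 (percentile 99.04), with 3 of 5 members higher, among them hey2 (19.9 and 57.6 CPM, ratio 2.89, 2.39 to 3.51) and irx1a (3.51 and 10.4 CPM), although its summed CPM was lower, 6714 and 5274, because vmhc makes up most of it.

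Cardiac transcription factors had a relative median of -0.12 (percentile 35.4), with 5 of 15 higher and 2 lower. Besides hand2 and tbx5a, the higher ones were tbx20 (20.1 and 59.9 CPM, ratio 2.97), tbx2b (12.3 and 27.7 CPM) and nkx2.7 (88.3 and 144 CPM). Lower was mef2ca (221 and 109 CPM, ratio 0.491, 0.447 to 0.539), beside srfb with only 18 and 5 UMIs. The reporter's own gene nkx2.5 was 846 and 802 CPM (ratio 0.948). Second heart field and arterial pole genes had a relative median of -0.04 (percentile 62.3), with hapln1a lower and bmp4 (171.5 and 286 CPM) and tgfb3 (44.7 and 77.9 CPM) higher. The other 7 of 10 lay between, tbx1 at 32.0 and 43.5 CPM among them. Pharyngeal mesoderm and head muscle genes stood at -0.38 (percentile 2.64), where nr2f1a and tcf21 (10.8 and 4.71 CPM) were among the lower members.

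Genes of endothelial specification, which are low in cardiomyocytes, lay above random lists in the Pbx4-depleted library, at a relative median of 0.56 (percentile 100). Of 13 measured members 7 were at least 1.5-fold higher and 0 lower, and their summed level was 40.7 and 89.6 CPM. Among them etv2 was 5.03 and 20.3 CPM (ratio 4.04, 2.81 to 5.89), lmo2 8.08 and 20.5 CPM, sox7 5.50 and 11.5 CPM and erg 1.29 and 5.08 CPM. At even depth the share of cardiomyocytes with etv2 was 2.20% and 3.73%, with a ratio interval (0.774 to 3.73) that held 1, and doublets with endothelial cells remain possible at such levels. The Notch pathway list stood at 0.30 (percentile 99.04), with 5 of 12 higher, among them hey2, her9 (109.5 and 177 CPM) and notch3 (4.22 and 8.85 CPM), and 0 lower. The TALE homeobox list stood at 0.26 (percentile 96.3), with meis1b (23.1 and 43.5 CPM), meis2a (9.25 and 21.1 CPM) and pknox1.2 higher and meis2b lower.

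Glycolysis and nuclear oxidative phosphorylation genes had medians below random lists. Glycolysis genes had a relative median of -0.46 (percentile 0), with 8 of 18 lower, among them ldha, tpi1b (269.5 and 176 CPM), gpia (79.1 and 44.1 CPM) and pgam1a (66.0 and 35.96 CPM), while gapdh (287.5 and 540 CPM), pgam2 (9.84 and 38.03 CPM) and pgam1b were higher, and the summed level of the list was also higher, 3022 and 3135 CPM. Nuclear oxidative phosphorylation genes stood at -0.31 (percentile 0), with 86 of 91 between the limits. Stress and heat shock genes stood at -0.28 (percentile 0.3), with 6 of 27 lower, among them hsp90aa1.1, hsp70.2 (357 and 213 CPM) and hsp70l (165 and 80.2 CPM). The summed level of the stress list was higher, 12460 and 13900 CPM. Without the subtraction its median was -0.10, with a counting interval (-0.135 to 0.080) that held 0.

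Of the other lists in cardiomyocytes, the retinoic acid and ribosomal protein lists lay below random lists and the rest within them. Relative medians were -0.36 for the retinoic acid pathway (percentile 2.03), with cyp26c1 at 17.1 and 7.91 CPM and rbp5 at 18.9 and 42.4 CPM, -0.35 for Wnt targets (6.14), -0.26 for 3 anterior Hox genes (22.7) and -0.25 for smooth muscle and extracellular matrix (4.38). They were -0.22 for cytosolic ribosomal proteins (0.665), -0.21 for damage response genes and cell cycle inhibitors (7.54), -0.10 for FGF targets (33.8), -0.07 for mitochondrially encoded genes (68.8, with summed levels of 20780 and 22350 CPM) and -0.03 for BMP and TGF-beta targets (59.5). In the last, bambib was 194 and 417 CPM (ratio 2.15). In the damage response list, mdm2 and cdkn1a had ratios of 0.874 (0.515 to 1.45) and 0.520 (0.238 to 1.05). The interferon list had only 2 measured members and gave no median. Without the subtraction of 0.18, the medians of the transcription factor, second heart field, FGF, BMP, S phase and mitochondrial lists lie above 0. Those of the second heart field, BMP and mitochondrial lists also lay above the middle of their random lists, by the percentiles given.

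Cell cycle genes gave no single direction in cardiomyocytes. The G2/M list had a relative median of -0.38 (percentile 0.0100), with cdk1 at 16.2 and 11.5 CPM and plk1 at 15.3 and 10.4 CPM, and its summed level was 1686 and 1659 CPM, most of it hmgb2a and hmgb2b. The S phase list had a relative median of -0.09, against 0.09 without the subtraction (percentile 24.4), with mcm2 at 14.8 and 25.8 CPM and mcm7 at 32.7 and 42.2 CPM, and its summed level was 564 and 605 CPM (ratio 1.07, 1.03 to 1.12). Before the subtraction, the G2/M median of cardiomyocytes was -0.20, and it was 0.06 when every cell had the same weight. It was also 0.06 without the 3% of cells with the highest doublet scores. Both alternative values lie above 0 but below 0.18.

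Shares of cardiomyocytes with cell cycle UMIs were higher in the Pbx4-depleted library. At 5000 UMIs per cell, 159 of 683 control cardiomyocytes (23.3%, 20.2 to 26.6) and 119 of 402 Pbx4-depleted ones (29.6%, 25.2 to 34.3) had at least 3 UMIs of the S phase list, and 474 of 683 (69.4%, 65.8 to 72.8) and 320 of 402 (79.6%, 75.3 to 83.4) had at least 3 UMIs of the G2/M list. The conditional binomial intervals of both ratios held 1 at this limit, but they are too wide for such high shares. The exact intervals of the G2/M shares did not overlap between the libraries, while those of the S phase shares did. At 5 UMIs the ratios were 1.445 (1.045 to 1.99) for S phase and 1.22 (1.02 to 1.45) for G2/M. Thinning left out 90 and 55 shallower cardiomyocytes, and median depths were 10233 and 11548 UMIs. Unthinned shares were 40.2% and 54.7% for S phase and 86.6% and 94.97% for G2/M. The G2/M share went against the median of its list, so no order is read from it, and how far free RNA of cell cycle genes sets either share is open, since no class examined for this lacks cycling cells. In pharyngeal mesoderm the S phase shares were 92.3% and 86.3% and the G2/M shares 99.7% and 99.6%, in endothelium or endocardium 85.7% and 81.5%, and 99.6% and 96.5%.

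Pharyngeal mesoderm of the Pbx4-depleted library had lower levels of lft2, hapln1a, the titin gene ttn.2 and the natriuretic peptide B gene nppb, and higher levels of sox4a, emx3, crip2 and fhl1a. Its clusters were mixed unevenly: control and Pbx4-depleted cells numbered 190 and 331 in cluster 1, and 211 and 286 in cluster 3. They numbered 221 and 217 in cluster 5, and 114 and 58 in cluster 11. Class sums and list medians can therefore differ through this mixture, not only within cells. Of the genes named by the fixed rule, the largest difference was in lft2, at 175 CPM in the control and 13.6 CPM in the Pbx4-depleted library (12.9-fold lower, 10.9 to 15.4). It was followed by hapln1a at 66.4 and 7.74 CPM (8.58-fold lower, 6.81 to 10.9) and elovl6 at 91.2 and 21.5 CPM (4.24-fold lower, 3.66 to 4.92). The transcription factor gene sox4a was first among the genes named as higher, at 128 and 399 CPM (ratio 3.13, 2.93 to 3.34), and it was higher in neural cells too (3.42, 2.497 to 4.71) and in free RNA (2.59). It was lower in cardiomyocytes (0.742, 0.661 to 0.831) and close in endothelium or endocardium (1.1, 0.908 to 1.33). Of the 24 genes named in this class, 11 were named again when cells were clustered without cell cycle genes and 13 when they were classed by marker scores.

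Other genes lower in Pbx4-depleted pharyngeal mesoderm were ttn.2 (359 and 116 CPM, 3.09-fold lower, 2.90 to 3.30), nppb, the natriuretic peptide B gene (183 and 61.0 CPM, 3.004-fold), and smtnl1, of the smoothelin family (54.6 and 18.1 CPM, 3.02-fold). Matrix and growth factor genes in this group were postnb (periostin, 55.8 and 14.5 CPM, 3.84-fold, 3.203 to 4.62) and ctgfa (connective tissue growth factor, 236.5 and 84.7 CPM, 2.79-fold, 2.58 to 3.02). The retinol esterification gene lratb was 53.3 and 16.0 CPM (3.33-fold), the apolipoprotein E gene apoeb 79.2 and 28.4 CPM (2.79-fold), csrp1a 153 and 64.1 CPM (2.38-fold) and stmn2a 64.6 and 20.3 CPM (3.18-fold). Cardiomyocyte markers such as ttn.2 and nppb had as a list a median log2 ratio of -0.28 in this class (percentile 0), with 5 of 20 members lower and 0 higher, while their summed level was 7310 and 7422 CPM.

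Other genes higher there were crip2 (53.5 and 179 CPM, ratio 3.35, 3.03 to 3.703), the homeobox gene emx3 (74.6 and 201 CPM, 2.695), kazald2 (40.8 and 112.5 CPM, 2.76), fhl1a (37.3 and 99.6 CPM, 2.67) and rasl11a (52.9 and 126 CPM, 2.38). The genes emx3, sox4a and tsc22d1 (45.5 and 98.7 CPM, 2.17) are among the leading genes of cluster 1. In pharyngeal cluster 3, sox4a was 68.3 and 139 CPM and emx3 5.33 and 28.5 CPM. The list was completed by tgfbi (29.6 and 67.8 CPM, 2.29), smarcd1 (121 and 252 CPM, 2.08), the tubulin gene tuba8l3 (99.03 and 194 CPM, 1.95), btf3 (1102 and 2034 CPM, 1.85) and a ferritin light chain copy (76.6 and 163 CPM, 2.12), whose reads may be shared with other copies of the gene. Many of these were higher outside the class too. Neural and free RNA ratios were 3.25 and 4.84 for kazald2, 4.45 and 2.78 for rasl11a, 2.41 and 2.38 for crip2 and 1.74 and 2.59 for smarcd1, and in free RNA emx3 had a ratio of 6.16.

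Endothelial specification genes lay above random lists in pharyngeal mesoderm too, at a median log2 ratio of 0.30 (percentile 98.2) and a summed level of 85.7 and 163 CPM. The counting interval of this median, -0.051 to 0.599, held 0. Without thinning, tal1 was seen in only 7 of 736 control and 29 of 892 Pbx4-depleted cells, and doublets with endothelial cells remain possible here as well. The 4 higher members of 12 were tal1 (0.769 and 9.88 CPM, ratio 12.8, 6.02 to 32.7), lmo2 (3.30 and 19.1 CPM, 5.795, 3.94 to 8.81), etv2 (7.58 and 38.8 CPM, 5.11, 3.96 to 6.70) and sox7 (40.8 and 71.1 CPM). The 2 lower were gata2a (11.3 and 4.29 CPM) and klf2a (4.62 and 1.77 CPM). The ratio intervals of the later endothelial genes kdrl, cdh5 and fli1a held 1. TALE homeobox genes had a median of 0.35 (percentile 99.9), with 5 of 12 higher, among them meis1b (48.9 and 77.2 CPM), meis3 (12.1 and 24.1 CPM) and pbx3b (5.06 and 10.1 CPM). Notch pathway genes had one of 0.29 (percentile 99.4), with hey2 at 45.0 and 67.7 CPM and dll4 at 5.61 and 11.6 CPM.

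Wnt targets were lower in Pbx4-depleted pharyngeal mesoderm, at a median of -0.36 (percentile 0.130), with 4 of 8 members lower and 0 higher: wif1 (41.4 and 16.96 CPM, ratio 0.409, 0.341 to 0.490), dkk1b (45.3 and 29.7 CPM), nkd1 (18.2 and 11.2 CPM) and sp5a (5.39 and 2.24 CPM). G2/M genes had a median of -0.22 (percentile 0), with cdk1 (129 and 104.5 CPM), plk1 (129.7 and 97.7 CPM) and aurka (69.4 and 47.0 CPM) among them. S phase genes had one of -0.11 (percentile 0.350), and of 0.14, the opposite direction, when cells were classed by marker scores. The G2/M median ranged more widely with the definition of the class than these values, at -0.69 when cells were clustered without cell cycle genes and 0.03 when they were classed by marker scores.

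The remaining lists in pharyngeal mesoderm had medians near 0. They were 0.21 for ventricular genes (percentile 88.4), 0.20 for 4 interferon genes (80.3), 0.10 for BMP and TGF-beta targets (81.7), 0.09 for smooth muscle and matrix (64.7), 0.06 for cardiac transcription factors (63.4), 0.06 for second heart field genes (60.2), and 0.05 for glycolysis (55.0). Nearer 0 were 0.03 for damage response genes and cell cycle inhibitors (44.4), 0.02 for FGF targets (43.1) and 0.01 for atrial genes (41.1). Below 0 stood ribosomal proteins at -0.02 (3.52), stress genes at -0.05 (5.27), the retinoic acid pathway at -0.07 (10.7), anterior Hox genes at -0.08 (26.6), sarcomere genes at -0.09 (2.56), pharyngeal and head muscle genes at -0.09 (10.4), oxidative phosphorylation at -0.11 (percentile 0) and mitochondrially encoded genes at -0.13 (1.15). Single members still differed: tbx1 was 213 and 282 CPM (ratio 1.33, 1.25 to 1.41), tbx20 6.92 and 19.8 CPM (2.85), isl2b 15.5 and 28.3 CPM (1.83), id3 504 and 898 CPM (1.78), and the retinoic acid degrading enzyme gene cyp26c1 347 and 209 CPM (0.603).

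**Figure D3:**
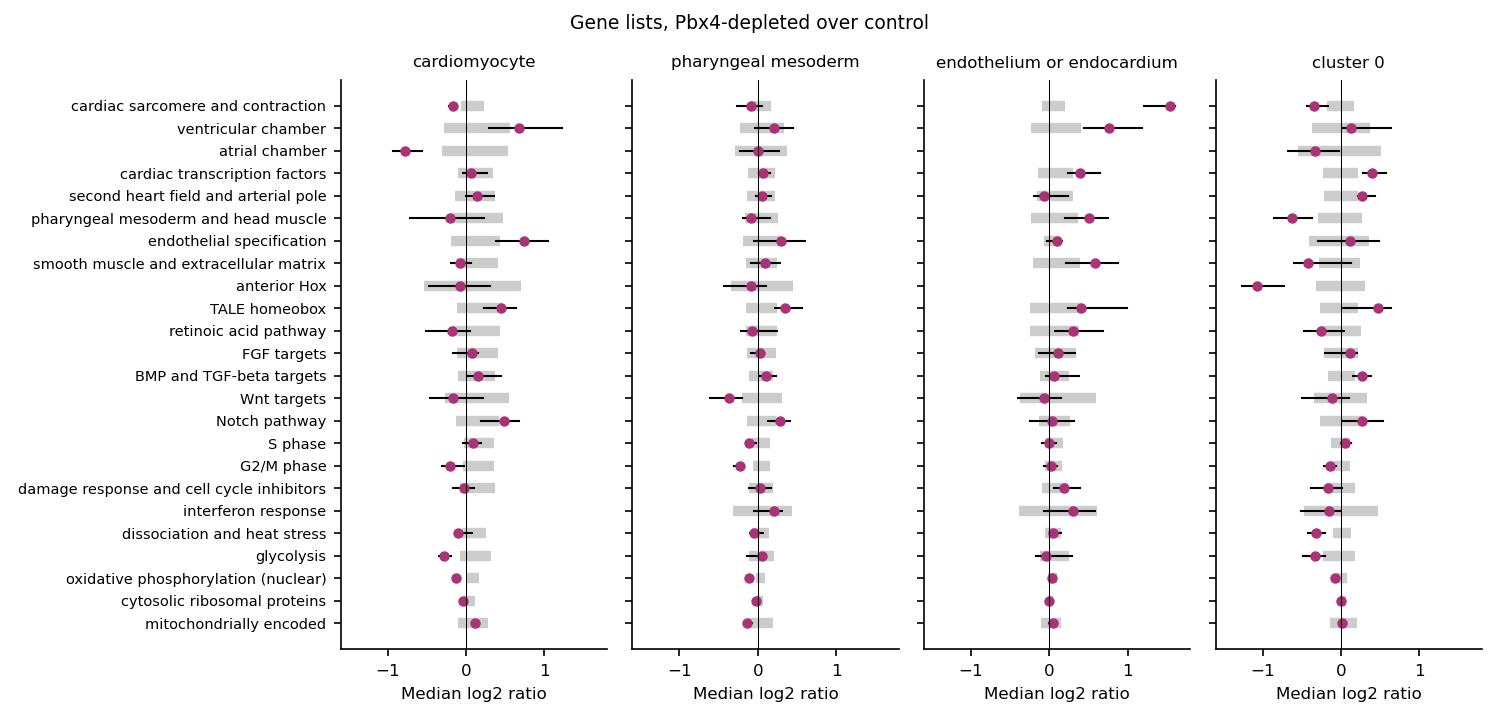
Median log2 ratio (Pbx4-depleted over control) of each program list in 4 groups of cells, as points with black lines for counting error from redrawn counts, and grey bars for the central 95% of random lists of the same size and expression. The sarcomere list lay at -0.17 in cardiomyocytes and 1.54 in endothelium or endocardium, and the anterior Hox list at -1.07 in cluster 0; values here are before the subtraction of 0.18 in cardiomyocytes.

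Endothelium or endocardium had similar levels of most endothelial genes, with tal1 and lmo2 higher. The list had a median of 0.10 (percentile 92.2), with 2 of 17 members higher, tal1 (306 and 526 CPM, ratio 1.72, 1.58 to 1.87) and lmo2 (810 and 1393 CPM, 1.72, 1.63 to 1.81), 0 lower and 15 between, among them etv2 (963 and 1272 CPM, 1.32), kdrl (240 and 183 CPM, 0.759, 0.675 to 0.853) and cdh5 (463 and 377 CPM, 0.812). Control and Pbx4-depleted cells numbered 119 and 116 in cluster 7, led by genes such as lmo2, and 124 and 72 in cluster 9, led by genes such as cdh5. They numbered 33 and 35 in cluster 19, led by lmo2, tal1 and etv2. This mixture stays open as a source of the differences in these genes. The sarcomere list stood at 1.54 (percentile 100), with 13 of 17 members higher and a summed level of 3271 and 6406 CPM (ratio 1.96, 1.91 to 2.01), myl7 at 271 and 1286 CPM and vmhc at 59.4 and 302 CPM. This lay mainly in cluster 7, where the summed level was 3600 and 9137 CPM against 3056 and 3136 CPM in cluster 9, and in few cells: the list made up over 0.5% of UMIs in 15 of 276 control and 35 of 223 Pbx4-depleted cells. The median cell had 2691 and 2925 CPM. Of other lists, the medians were 0.76 for ventricular genes (99.8), 0.58 for smooth muscle and matrix (99.8), 0.50 for pharyngeal and head muscle genes (99.6), 0.41 for TALE homeobox genes (97.4) and 0.39 for cardiac transcription factors (99.6). The sarcomere median was 0.94 when every cell had the same weight and 3.14 after subtraction of free RNA.

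Cluster 0, an unnamed group led by the retinoic acid synthesis genes rdh10a and aldh1a2 with isl2a and meis3, had lower anterior Hox and higher cardiac transcription factor levels in the Pbx4-depleted library. Of 8 measured anterior Hox genes 7 were at least 1.5-fold lower and 0 higher, at a median of -1.07 (percentile 0) and a summed level of 347 and 192 CPM. Among them hoxb3a was 128 and 82.0 CPM (ratio 0.639, 0.555 to 0.734), hoxb1b 97.7 and 58.5 CPM (0.599, 0.508 to 0.705), hoxa4a 55.4 and 25.8 CPM (0.465) and hoxa2b 22.0 and 6.44 CPM (0.293). Cardiac transcription factors stood at 0.39 (percentile 99.96), with nkx2.5 at 683 and 952 CPM (1.39, 1.33 to 1.46), hand2 at 103 and 240 CPM (2.34, 2.09 to 2.62), nkx2.7 at 203 and 322 CPM and tbx20 at 2.06 and 8.51 CPM higher, and mef2ca lower. Pharyngeal and head muscle genes stood at -0.63 (percentile 0), with 5 of 10 lower, among them tcf21 (47.4 and 27.1 CPM), while tbx1 was 165 and 244 CPM.

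Other lists of cluster 0 that lay outside random lists were TALE homeobox (0.47), second heart field genes (0.27), BMP and TGF-beta targets (0.27) and the Notch pathway (0.26) above, and smooth muscle and matrix (-0.43), sarcomere (-0.35), glycolysis (-0.34), stress genes (-0.32), G2/M (-0.14) and oxidative phosphorylation (-0.08) below. In the stress list fosab was 1562 and 1003 CPM and hsp70l 216 and 82.7 CPM. At resolution 2.0 the matching cluster held 8.81% of control and 4.21% of Pbx4-depleted cells, a ratio of 0.479 beside 1.16 at resolution 1, and another unnamed cluster led by kazald2 held mostly Pbx4-depleted cells. There the anterior Hox median was -0.40 and that of cardiac transcription factors near 0, and those of second heart field genes (-0.0286), BMP and TGF-beta targets (-0.0329) and G2/M genes (0.15) were opposite in direction to those above.

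Lineage genes were also read as shares of cells with a UMI at 5000 UMIs per cell. Cells of the neural class, which should lack most of these genes, give the background, at median depths of 7748 and 8398 UMIs. In cardiomyocytes, hand2 was seen in 161 of 683 control cells (23.6%, 20.4 to 26.9) and 219 of 402 Pbx4-depleted cells (54.5%, 49.5 to 59.4), a ratio of 2.31 (1.88 to 2.85), beside 7.95% and 4.11% of neural cells. The unthinned shares were 40.0% and 72.4%. Cells with myh6 were 30.6% (27.2 to 34.2) and 17.4% (13.8 to 21.5), beside 1.32% and 2.74% in neural cells, and 41.8% and 24.7% unthinned. The mixture of cardiomyocyte clusters, which differed between the libraries, can also set the myh6 shares. Cells with vmhc were 99.6% and 94.8%, with gata6 43.8% and 53.7% and with tbx1 11.4% and 18.7%, beside 26.5% and 24.7%, 1.99% and 2.74%, and 2.65% and 5.48% of neural cells.

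In pharyngeal mesoderm, where median depths were 11230 and 10910 UMIs and thinning left out 46 and 58 cells, etv2 was seen in 20 of 690 control cells (2.90%, 1.78 to 4.44) and 57 of 834 Pbx4-depleted cells (6.835%, 5.22 to 8.77), a ratio of 2.36 (1.40 to 4.14), beside 1.32% (0.161 to 4.70) and 1.37% (0.0347 to 7.40) of neural cells, intervals that hold both shares. The unthinned shares were 6.11% and 11.7%, and at 2 or more UMIs the ratio was 5.79. Likewise, shares with tal1, 0.435% and 1.56%, and with kdrl, 1.01% and 0.480%, lay within the intervals of the neural shares, which for both genes were 1.99% (0.412 to 5.70) and 1.37% (0.0347 to 7.40). Cells with tbx1 were 57.5% (53.8 to 61.3) and 64.75%, with tcf21 24.5% and 23.9%, with hand2 30.3% and 32.3%, and with nkx2.5 71.4% and 75.5%, beside 11.9% and 26.0% of neural cells. Cells with isl1 were 2.61% and 4.20%, with no clean background because neurons can express this gene. The gene myl7 was seen in 60.3% and 58.9% of neural cells, so its shares of 73.5% and 73.9% in pharyngeal mesoderm are not read as expression. Shares with gata4 in cardiomyocytes were 0.586% and 0.746%, and gata5 was seen in 9.22% and 8.71% of cardiomyocytes.

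**Figure D4:**
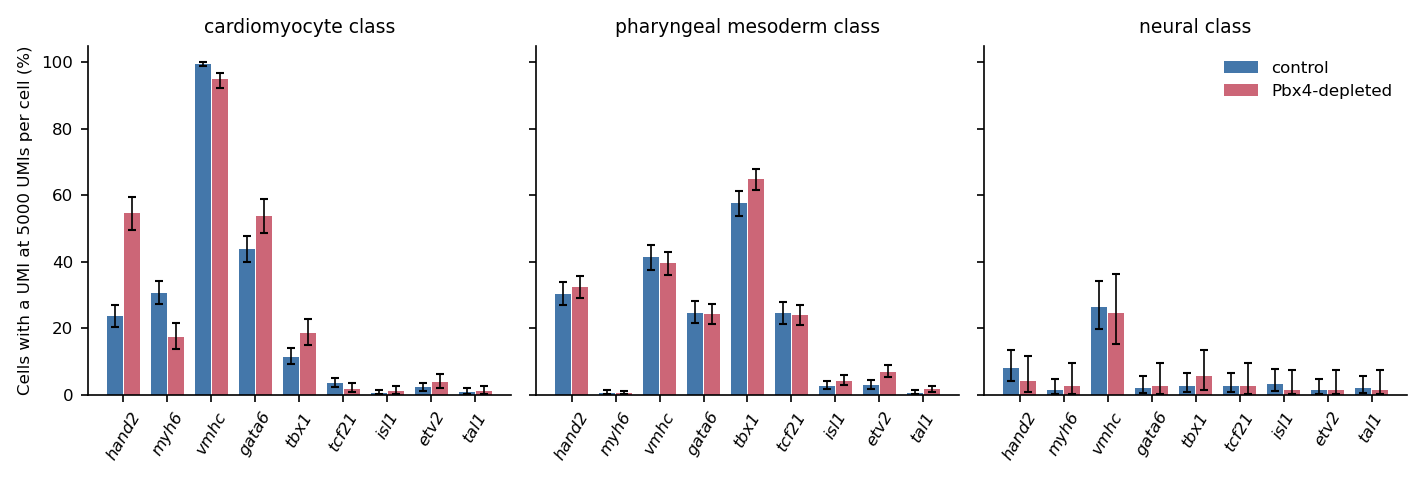
Share of cells (percent) with at least 1 UMI of 9 lineage genes after thinning to 5000 UMIs per cell, in cardiomyocytes, pharyngeal mesoderm and the neural class that serves as background, with exact Clopper-Pearson 95% intervals. In cardiomyocytes hand2 stood at 23.6% in the control and 54.5% in the Pbx4-depleted library, and myh6 at 30.6% and 17.4%.

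Over all called cells, the named genes mixed differences within classes with the different shares of the classes. Lower in the Pbx4-depleted library were lft2 (393 and 54.3 CPM, 7.24-fold, 6.87 to 7.64), hapln1a (454 and 65.8 CPM, 6.90-fold), apln (53.2 and 12.5 CPM, 4.27-fold), atp2a2a (156 and 50.9 CPM, 3.06-fold), nppb (542 and 212 CPM, 2.56-fold) and smtnl1 (288 and 112 CPM, 2.57-fold). Skeletal muscle genes mylpfa (172 and 50.5 CPM), mylz3 (115 and 40.9 CPM) and tpma (158 and 55.7 CPM) were lower too, as were the epithelial adhesion gene epcam (121.5 and 39.9 CPM), cfl1l (233 and 96.3 CPM) and tmsb1 (178 and 63.7 CPM). Higher were kazald2 (31.1 and 102.5 CPM, ratio 3.295), emx3 (24.6 and 86.3 CPM, 3.51), lyz, the lysozyme gene of myeloid cells (10.0 and 50.2 CPM, 5.00, 4.45 to 5.64), sox4a (95.2 and 229.9 CPM, 2.41), and sox11b (64.1 and 147 CPM, 2.3). So were stc2a (96.2 and 232 CPM, 2.41), rasl11a (32.6 and 88.7 CPM, 2.72), crip2 (144 and 312 CPM, 2.17), fhl1a (81.4 and 185 CPM, 2.28), smarcd1 (91.8 and 205 CPM, 2.23), snrpd1 (581 and 1150 CPM, 1.98) and id3 (288 and 557 CPM, 1.935).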

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

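All tests described here were chosen only after the results were seen, and the differences listed without a test were not followed further.

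The sarcomere list had a median log2 ratio of 1.54 in endothelium or endocardium of the Pbx4-depleted library, against -0.17 in cardiomyocytes and -0.35 in cluster 0. The cardiomyocyte value here is before the subtraction of 0.18 used in the results. Free cardiac RNA is excluded as the whole cause, because the summed sarcomere level in neural cells had a ratio of only 1.18 (1.13 to 1.24) beside 1.96 (1.91 to 2.01) in the endothelial class. Neural cells do not hold free RNA alone, as 10 of 196 control and 6 of 106 Pbx4-depleted ones had over 0.5% of their UMIs from the list. In the endothelial class 35 of 223 Pbx4-depleted cells (15.7%, 11.2 to 21.2) and 15 of 276 control cells (5.43%, 3.07 to 8.81) were over that limit, while the median cell carried the list at 2691 CPM in the control and 2925 CPM in the Pbx4-depleted library. Droplets with a cardiac and an endothelial cell stay open, as these Pbx4-depleted cells had a median doublet score of 0.0518 beside 0.0160 in the others and 13226 beside 9836 UMIs. In the control such cells had scores of 0.0328 beside 0.0156 but fewer UMIs, 9968 beside 11132. Without the 3% of cells with the highest doublet scores the list median was 1.83. A mixed endocardial and myocardial state stays open too, since the control library holds more cardiomyocytes yet has the smaller share of such cells.

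The list of pharyngeal mesoderm and head muscle genes had a median of -0.63 in cluster 0 and 0.50 in endothelium or endocardium, where ebf3a was 7.80 and 18.8 CPM, and this difference was not tested. Among barcodes with 10 to 100 UMIs, which are not called cells, emx3 was 17.8 and 109 CPM (ratio 6.16, 3.54 to 10.9) and kazald2 35.5 and 172 CPM (4.84, 3.21 to 7.32). A ferritin light chain copy was 44.8 and 197 CPM (4.40, 3.03 to 6.39). This range can take unlike barcodes from the 2 libraries, and the cause of these differences was not tested.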

How the results depend on the processing

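Of the alternatives, those that left out the cells with the highest doublet scores, cardiomyocyte cluster 17 or pharyngeal cluster 11 were chosen after the data were seen, and the others before.

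Of 1444 list medians under an alternative, 1289 stayed close, 145 moved and 10 changed direction, and of 888 ratios of named genes 769 stayed close, 119 moved and 0 changed direction. A value stayed close when it lay within the 95% counting interval of the reported value, and a number of cells or shared genes when it was within 1.5-fold. A change of direction was counted only where the reported interval left out equality, and for a list only if it also lay outside random lists. Named genes were chosen for large ratios in these same data, so a change of direction among them was unlikely from the start. Some alternatives hardly changed the cells: 1 barcode per library was over the mitochondrial maximum, and 1 and 3 were called doublets. Such settings raise the numbers that stayed close. List medians in this paragraph are before the subtraction of 0.18 in cardiomyocytes. Cells called in the Pbx4-depleted library were 3846 with the 4000 barcodes of most UMIs. The ratio of cardiomyocyte shares was 0.601 with clustering without cell cycle genes, and that of pharyngeal mesoderm 1.32 with classes from marker scores. In cardiomyocytes, pbx4 had a log2 ratio of 0.27 with median-of-ratios scaling. The sarcomere median, -0.17 before the subtraction, was -0.14 without cell cycle genes. With median-of-ratios scaling, which makes the same subtraction, it was -0.35, the relative median given in the results. The G2/M median in cardiomyocytes, -0.20 before the subtraction, was 0.0647 with the mean of per-cell CPM and 0.0603 without the cells of highest doublet scores. Both are opposite in direction on this scale only. They lie below the 0.18 of the main setting, and relative medians were not computed for these alternatives. The G2/M median was -0.32 without cell cycle genes, -0.33 with marker scores, -0.32 after subtraction of free RNA and -0.31 without cluster 17. With median-of-ratios scaling it was -0.38, the relative median given in the results. In pharyngeal mesoderm the G2/M median was 0.0319, the opposite direction, with marker scores. It was -0.0350 at resolution 2.0, -0.69 without cell cycle genes, -0.34 with per-cell means and -0.32 without cluster 11. With marker scores the S phase median there was 0.14, opposite in direction, and pbx4 had a log2 ratio of -0.12 against 0.11. Of the 24 genes named in pharyngeal mesoderm, 11 were named again without cell cycle genes and 13 with marker scores. The mitochondrially encoded median there was 0.00204 without cell cycle genes, and the head muscle median of all cells 0.00840 with per-cell means, both opposite in direction. In endothelium or endocardium the sarcomere median was 1.21 with called doublets kept, 1.83 without the highest doublet scores, 0.94 with per-cell means, 3.14 after subtraction of free RNA and 1.03 without a UMI minimum per gene. In cluster 0 the anterior Hox median was -0.40 at resolution 2.0 and -0.64 without a UMI minimum. At resolution 2.0 the cluster 0 medians of cardiac transcription factors (-0.00126), second heart field genes (-0.0286), BMP and TGF-beta targets (-0.0329) and G2/M genes (0.15) were opposite in direction. The ratio of shares of cardiomyocytes with hand2 was 1.81 without thinning and 3.85 at 2 or more UMIs, where that of tbx1 in cardiomyocytes was 1.13 and that of etv2 in pharyngeal mesoderm 5.79. At 2 or more UMIs tal1 gave no ratio in pharyngeal mesoderm, because the control had 0 such cells. The cause was not tested for any of these.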

Other observations

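The test on thinned cardiomyocytes was written before its result was seen, and the other tests here were chosen only after the results were seen.

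The transcripts of btf3 and malat1 each differed in the same direction in 4 classes, a pattern noted after the values were seen. The gene btf3 was 956 and 2010 CPM in cardiomyocytes, 1102 and 2034 CPM in pharyngeal mesoderm, 1086 and 2040 CPM in endothelium or endocardium, 1361 and 2169 CPM in neural cells and 949 and 1868 CPM in free RNA. The noncoding RNA malat1 had ratios of 0.531, 0.548, 0.486 and 0.552 in the same 4 classes and 0.942 (0.907 to 0.979) in free RNA. Differences shared by cells outside the heart, and for btf3 by the barcodes read as free RNA, may come from the embryo pool or the library preparation. With 1 library per group this cannot be told from an effect of the depletion. The free RNA values can also reflect which barcodes were taken in each library.

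The left-sided genes lft2 and lft1 were lower in both cardiac and pharyngeal cells of the Pbx4-depleted library, lft1, singled out after its values were seen, at 19.9 and 3.95 CPM in cardiomyocytes. For lft2 in cardiomyocytes, free RNA in the control is excluded, because lft2 was only 19.8 CPM (14.2 to 26.9) in its neural cells, beside a difference of 1104 CPM, and for lft1 and for pharyngeal cells this was not tested. Another mixture of cardiomyocyte clusters stays open for lft2: its log2 ratio within cluster 2 was -2.58 (-2.71 to -2.45), but at resolution 2.0 most of these cells parted by library, and no part held 50 cells of each, though lft2 was 524.4 and 36.6 CPM in a part of 42 and 39 cells. The fatty acid elongase gene elovl6 followed the same pattern, at 98.1 and 21.2 CPM in cluster 2 and 16.9 and 16.0 CPM in neural cells. The lft2 and lft1 values may reflect altered left-right signalling, which was not tested, and a pool of embryos with another laterality stays open.

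Cardiomyocytes had mostly neighbours of their own library, 82.1% (78.7 to 85.1) of 15 nearest neighbours where even mixing gives 49.8%. The value was 71.0% (66.3 to 75.0) in cluster 0, 62.3% in pharyngeal mesoderm and 53.2% in endothelium or endocardium. These neighbour percentages were taken over 20 draws of 100 cells per library. The bounds beside each neighbour percentage, thinned cells included, are the lowest and highest draw, not a confidence interval. For a shift of all cells of a library, the neural class was examined and stood at 52.0% (50.8 to 55.1). With endothelium or endocardium at 53.2%, a shift that parts neighbours equally in every class was not seen. The neural class cannot exclude a shift, because it mixes cell types, is shallower and was not thinned here. Its range is also narrow because each draw took 100 of its 106 Pbx4-depleted cells. A difference in depth is excluded, because cardiomyocytes thinned to even depth stood at 82.3% (77.3 to 85.6). A DNA damage response stays open, because mdm2 and cdkn1a together had a ratio of 0.724 (0.474 to 1.09) from few UMIs while the summed level of the damage response and cell cycle inhibitor list was higher, 2149 and 2636 CPM. An effect on cardiomyocytes and a difference in stage or sorted cells between the pools both stay open.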
